A study of Mus musculus with 138 samples.

How the data were processed

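Total RNA from lung was measured on Illumina WG6v2 bead arrays in 138 mice, 1 array per mouse and 1 mouse per line. Per the labels' protocols, lung lobes were homogenised and RNA was purified on columns and treated with DNase before amplification and biotin labelling. The values used come in 3 units. The deposited scanner table gives an intensity per probe and array, which was not normalized, and per the file headers a detection p-value beside each intensity. The authors also deposited normalized log2 values of the same arrays. Per the series' design text and the submitters' processing notes these were made with GenomeStudio and then R 2.9.2, by RMA with quantile normalization and log2 transformation. Whether a background correction was part of that step is not given in the sources used here. Every column of the deposited log2 values had a median of 5.57, with values from 4.68 to 13.4, and each of the 138 columns correlated best with the scanner intensities of its own array (r from 0.9959 to 0.99996). Scale and direction are therefore known, and the genes were not centred.

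The main values were computed from the scanner table with limma 3.58.1 in R 4.3.3. The neqc step fits the background from the detection p-values, adds an offset of 16, normalizes by quantiles over arrays and takes log2. Probes with a detection p under 0.05 in at least 14 of the 138 mice were kept, which left 24450 of 45281 probes. Probes were named from the target name in the scanner table, brought up to date through the RefSeq gene table of assembly GRCm38.p6. Of all probes, 22864 matched a current symbol, 11917 a unique synonym and 10500 kept the name in the file, which is then printed as the file gives it (SPRR2A, ITLNB). A gene was represented by its kept probe with the highest mean, which gave 16617 genes, of which 5319 had more than 1 kept probe. The reference table was otherwise used only to find which genes neighbour each other, and no coordinates were taken from it. Probe sequences and positions were not used here.

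The labels give 1 group, so no groups were compared except in the test of the title number described at the end of the report. The design, the tests, 34 gene lists (15 functions and 19 cell types), 32 gene pairs, the rule for named genes and most alternatives were chosen before the data were examined. A list score is the mean, over the kept genes of a list, of their z values across mice. Each gene outside the list was fitted on a score with limma (lmFit and eBayes). The slope is in log2 per SD of the score, and p was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Counts adjusted over the list alone use the members of that list in place of all genes. Lists with fewer than 3 kept genes were not tested, which left out thymus (2 kept genes). Whether the genes of a list vary together was tested by their mean pairwise Pearson r against 10000 random lists matched in size and in 10 bins of mean expression, one-sided. Correlations of scores and of gene pairs were tested with 100000 permutations, two-sided, and repeated without the 2 mice farthest from the median. The smallest p these tests can give is 0.0001 for random lists and 1e-05 for permutations.

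A gene was called to have 2 separated levels when a mixture of 2 normal distributions lowered the BIC by more than 10 against a single normal, the means lay over 3 pooled SDs and over 1 log2 apart, and the smaller component held at least 5% of mice. The mixture was started from 5 quantiles and run for 200 iterations, with a floor of 0.05 log2 on each SD. Intervals of the SD between mice are 95% percentile bootstrap intervals over mice (2000 draws). These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

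For each score fit the text names up to 12 genes per direction, those with the largest slopes past the threshold that are outside the list and detected in at least 69 mice. For spread and for separated levels it names the 15 genes with the largest values, and members of the fixed lists and pairs may be named as well. Names of the form of a clone or a predicted gene were passed over, as were a few genes not reported here. The steps were tested on simulated normal values, mostly with the means and SDs of the real genes, and independent apart from what was planted. Such values lack the correlation between genes and the floor of the real data. The false calls given here therefore do not carry over to the real genes. In the score fit on 16617 genes, 8.0% of 100 genes with a planted slope of 0.2 of their own SD and 100% of those with 0.5 were recovered, with 9 false calls. The search for 2 levels, on 2000 genes, found 88.0% of 100 genes with a gap of 1.5 log2 and 100% of those with 3, with 0 false calls. The test of 15 lists recovered 93.3% at a planted mean r of 0.05 and 100% at 0.2, and the permutation test found 91.0% of 100 pairs at r = 0.3 with 3 false calls.

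Alternatives were the authors' deposited values, no background correction, no filter on dim probes, detection in every mouse, the mean of a gene's probes, covariates for the title number, the number of detected probes, tissue scores and lymphocyte scores, the rank of a score, and fits without the 2 farthest mice. Further alternatives were added after the data had been seen. They were the removal of a trend along the deposited table, the omission of 1 mouse or of the 2 mice highest on the interferon gamma score, the removal of genes with 2 levels from a score, and the type 2 immune, mucous, cardiac muscle, airway (cardiac muscle, adipose, ciliated and smooth muscle together) or RNA-form score as a covariate, the last made from nuclear and unspliced transcripts. That list and the lists of liver and skeletal muscle genes were added after the data had been seen. Arrays could not be tested by slide, since the files used here name no slides. The mice whose title and strain label disagree (2 of them) were left out of the test of the title number only.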

Results

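Lung RNA was measured in 138 mice of the incipient Collaborative Cross, a panel of lines bred from 8 founder strains. Per the labels, each mouse was sensitized with 10 ug of the house dust mite allergen Der p 1, challenged with 50 ug on day 15 and sampled on day 18, 72 hours after the challenge. Each line gave 1 mouse and there were no untreated mice, so the comparisons are across mice and none shows an effect of the allergen. Per array, 19075 to 21472 of 45281 probes were detected (median 20426.5), and the array median of the unprocessed signal was 32.1 to 68.7. Pairs of arrays correlated across all 45281 probes, also those not detected, at 0.886 to 0.9866 (median 0.967), and genes are not independent replicates. The number of arrays limits the precision. Levels are normalized log2 intensities of 16617 genes.

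The SD between mice was over 1 log2 for 9 of 11 genes of mucus production and for 6 of 16 genes of the type 2 response, the arm of immunity active in allergy, against 4.12% of all genes. Some other lists had such shares too: 5 of 9 cardiac muscle, 4 of 10 neutrophil, 3 of 7 MHC class II and 3 of 7 club cell genes. The count was 0 of 13 for T cell and 0 of 10 for B and plasma cell genes. Spreads depend on the processing, and 2.27% of all genes passed in the authors' deposited values. Other type 2 genes, such as the cytokines Il13 (mean level 4.95) and Il5 (4.80), lay near the floor of the scale, where their spread cannot be read. Clca1, a secreted goblet cell protein listed in the scanner table under its old name CLCA3, had a mean level of 10.82 ± 2.25 (SD, n = 138), and its 95th percentile lay 138-fold above its 5th. The same ratio was 55.6-fold for Muc5ac, a gel-forming mucin, 47.7-fold for Arg1, an arginase of alternatively activated macrophages, and 35.9-fold for Ccl11, an eosinophil chemokine. It was 18.4-fold for the mucin Muc5b and 19.8-fold for the chemokine Ccl24. The 5th percentiles of Clca1, Muc5ac, Arg1, Ccl11 and Ccl24 lay under 6, near the floor, so these ratios are not exact. Chil3, a chitinase-like protein of macrophages, spanned 7.63-fold. Retnla, another marker of alternatively activated macrophages, was high in the panel (12.39 ± 0.70) and spanned 2.46-fold. Its 95th percentile of 12.9 lay near the top of the scale, so its spread is hard to read. Scgb1a1, the main secreted protein of club cells, lay at the top of the scale (mean 13.13, highest value 13.35), where its spread cannot be read.

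The first question was which genes follow the mucous score, the mean z value of 11 genes of mucus production. The small proline-rich gene SPRR2A rose by 1.51 ± 0.10 log2 per SD of the score (slope ± SE, n = 138, adjusted p = 1.04e-28), and Capn9, a protease of the gut epithelium, by 1.22 ± 0.06 (9.32e-42). Retnlb, a goblet cell resistin-like protein, rose by 1.10 ± 0.08 (1.32e-22) and Ern2, the stress sensor of mucous cells, by 0.97 ± 0.06 (1.78e-30). The intelectin ITLNB (1.32 ± 0.18), the actin-severing protein gene Scin (1.26 ± 0.10), the antimicrobial lectin Reg3g (1.14 ± 0.12), the ion transport regulator Fxyd4 (1.02 ± 0.11), the adrenergic receptor Adra2a (0.94 ± 0.09) and Arg1 (0.94 ± 0.12) rose as well. So did 2 genes of heart atria, Nppa, a natriuretic peptide (1.18 ± 0.17), and Sln, a regulator of the calcium pump (0.91 ± 0.14).

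Cav2, a caveolin of flat alveolar and endothelial cells, had the slope -0.39 ± 0.08 (adjusted p = 3.98e-05). Foxf1, a transcription factor of lung mesenchyme and capillaries (-0.32 ± 0.09), the zinc transporter Slc39a8 (-0.35 ± 0.08), the binding protein Igfbp3 (-0.35 ± 0.09) and the actin-severing protein gene Gsn (-0.43 ± 0.10) fell too. The detoxifying enzymes Pon1 (-0.35 ± 0.07) and Ugt1a6a (-0.33 ± 0.07), the gluconeogenic enzyme Fbp2 (-0.37 ± 0.13), the membrane-shaping gene Sh3glb1 (-0.37 ± 0.12), the chemokine receptor IL8RA (-0.32 ± 0.09), the collagen processing enhancer Pcolce2 (-0.31 ± 0.06) and the ubiquitin ligase Rnf13 (-0.31 ± 0.06) also fell. Sh3glb1 had 2 separated levels (4.54 in 16 mice and 8.96 in the rest), so its slope depends on which mice were low. The same holds for Fxyd4 and Sln, named above, which also had 2 separated levels. By limma, 3757 genes outside the list passed, of which 1942 rose and 1815 fell. The count was 1784 with the type 2 immune score as a covariate. It was 2329 with cardiac muscle, adipose, ciliated and smooth muscle scores as covariates. With the type 2 immune score as a covariate the slope of Pon1 was 0.004, and Foxf1, Igfbp3, Ugt1a6a, IL8RA and Fbp2 were no longer called. With cardiac muscle, adipose, ciliated and smooth muscle scores as covariates Gsn, Slc39a8, Sh3glb1, Foxf1, Igfbp3 and Fbp2 were not called, and Fbp2 lost its call under 7 alternatives in all, IL8RA with T cell and B cell scores too, and Sh3glb1 without the filter.

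All 16 type 2 immune genes rose with the mucous score, and all 16 when adjusted over the list alone. Ccl8, a monocyte and eosinophil chemokine, rose by 0.77 ± 0.10 (adjusted p = 3.7e-10), Ccl24 by 0.63 ± 0.11, the chitinase-like gene Chil4 by 0.61 ± 0.08, Retnla by 0.37 ± 0.05 and the cytokine Il13 by 0.07 ± 0.02 (0.0108). Il13, Il5, Il1rl1 and Alox15 of this list lay near the floor (mean levels 4.95, 4.80, 4.99 and 4.63). Their rises can therefore not be read as firm changes of transcript level. Eosinophil markers rose in 4 of 7 cases (4 adjusted over the list alone), proliferation genes in 7 of 9 (7 adjusted over the list alone) and T cell markers in 7 of 13 (7 adjusted over the list alone). Smooth muscle genes rose in 7 of 8 cases, 7 adjusted over the list alone, with the contractile actin Actg2 at 0.32 ± 0.08. The secretory gene Scgb3a1 (0.83 ± 0.14) and the cilium regulator Foxj1 (0.12 ± 0.02) rose, with 2 of 10 ciliated genes in all (2 adjusted over the list alone). Markers of alveolar type 2 cells fell in 4 of 9 cases (4 adjusted over the list alone), among them Sftpb (-0.11 ± 0.03) and Lamp3 (-0.19 ± 0.05), and those of flat type 1 cells in 3 of 9 (4 adjusted over the list alone), among them Ager (-0.06 ± 0.02). Genes of xenobiotic metabolism fell in 4 of 13 cases, and 5 fell and 1 rose when adjusted over the list alone. Of 10 neutrophil genes, 2 rose (2 adjusted over the list alone), Retnlg (0.67 ± 0.07) and Ltf (0.64 ± 0.09), and 0 of 10 B and plasma cell genes passed on either adjustment. All 9 cardiac muscle genes rose, also when adjusted over the list alone, among them the heavy chain Myh6 (0.85 ± 0.12, adjusted p = 3.66e-08), the light chain Myl7 (0.70 ± 0.13) and the calcium channel Ryr2 (0.38 ± 0.06). All 3 adipose genes also rose (3 adjusted over the list alone), with the secreted protease Cfd at 0.68 ± 0.17. Myh6, Cfd and Scgb3a1 had 2 separated levels, so their slopes depend on which mice were low. Of 8 skeletal muscle genes, a list added after the data had been seen, 6 rose (6 adjusted over the list alone), and 4 without the mouse of line OR5308, in which these genes were highest.

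The next question was which genes follow the type 2 immune score, the mean z value of 16 cytokine, chemokine and macrophage genes. All 11 mucous genes rose with it (11 adjusted over the list alone), among them Clca1 by 1.30 ± 0.16 (adjusted p = 1.08e-11), the anion exchanger Slc26a4 by 1.18 ± 0.07 (6.83e-32), Muc5ac by 1.05 ± 0.13 (4.15e-11) and the trefoil peptide Tff1 by 0.80 ± 0.14. SPRR2A rose by 1.31 ± 0.12 (1.88e-18), the eosinophil ribonuclease family gene Rnase2a by 1.11 ± 0.09 (1.15e-22) and the macrophage elastase Mmp12 by 0.84 ± 0.07 (6.65e-19). Fxyd4 (1.18 ± 0.10), ITLNB (1.07 ± 0.19), Retnlb (1.03 ± 0.09), Scin (0.85 ± 0.13) and the protease inhibitor Serpina3g (0.80 ± 0.11) completed the largest slopes. Muc5ac and Fxyd4, and Cavin1 among the falling genes below, had 2 separated levels, so their slopes depend on which mice were low. Pon1 (-0.55 ± 0.06, adjusted p = 5.54e-13) and the aldehyde dehydrogenase Aldh3a1 (-0.36 ± 0.05) fell, as did Bex2 (-0.46 ± 0.07), the endothelial proteoglycan Esm1 (-0.44 ± 0.11), Igfbp3 (-0.39 ± 0.09), the vesicle transport gene Rab6b (-0.39 ± 0.05), Fbp2 (-0.38 ± 0.13), the caveola protein Cavin1 (-0.37 ± 0.13, by a probe that another kept probe of the gene does not follow, r = 0.081), Aard (-0.35 ± 0.10), Acoxl (-0.34 ± 0.06), the asialoglycoprotein receptor Asgr1 (-0.34 ± 0.07) and IL8RA (-0.34 ± 0.09).

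T cell markers rose with the type 2 immune score in 12 of 13 cases (12 adjusted over the list alone), among them the costimulatory receptors Ctla4 (0.30 ± 0.04) and Icos (0.26 ± 0.03). Eosinophil genes rose in 5 of 7 cases (5 adjusted over the list alone), with the granule protein Prg2 at 0.76 ± 0.09 (adjusted p = 3.48e-12) and the transcription factor Cebpe at 0.52 ± 0.05 (2.24e-18). Genes of neutrophilic inflammation rose in 7 of 8 cases (7 adjusted over the list alone), including the chemokine Cxcl1 (0.60 ± 0.08) and the acute phase gene Saa3 (0.64 ± 0.11). Genes of the interferon gamma response rose in 5 of 8 cases (8 adjusted over the list alone), with the chemokines Cxcl9 at 0.68 ± 0.10 and Cxcl10 at 0.56 ± 0.08, but without the mice of lines OR5513 and OR1427, whose interferon gamma scores of 4.11 and 3.22 stood far above all others (at most 1.5), 3 of 8 rose (3 adjusted over the list alone), with Cxcl9 at 0.55 ± 0.09 and Cxcl10 at 0.47 ± 0.08. The wider interferon response rose in 7 of 13 cases (9 adjusted over the list alone), MHC class II genes in 4 of 7 (5 adjusted over the list alone), monocyte and dendritic cell markers in 7 of 10 (7 adjusted over the list alone) and proliferation genes in 8 of 9 (8 adjusted over the list alone). Matrix genes rose in 5 of 11 cases, and 1 fell (5 and 1 adjusted over the list alone), with the protease inhibitor Timp1 at 0.66 ± 0.07. Xenobiotic genes fell in 7 of 13 cases and 1 rose, against 10 and 1 adjusted over the list alone. Type 1 alveolar markers fell in 5 of 9 cases (5 adjusted over the list alone). Among them was Rtkn2 at -0.14 ± 0.02, by a probe that another kept probe of the gene does not follow (r = -0.178). None of the 9 cardiac muscle and 3 adipose genes passed, on either adjustment. By limma, 4014 genes outside the list passed, 1984 of them rising and 2030 falling. With the mucous score as a covariate, ITLNB, Scin, Igfbp3, Fbp2, Cavin1 and IL8RA were no longer called. Cavin1 lost its call under 5 alternatives, Fbp2 under 3, and Esm1 and IL8RA with T cell and B cell scores as covariates. Among genes detected in every mouse, with the score rebuilt from the list genes left there, 2348 genes passed.

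**Figure D1:**
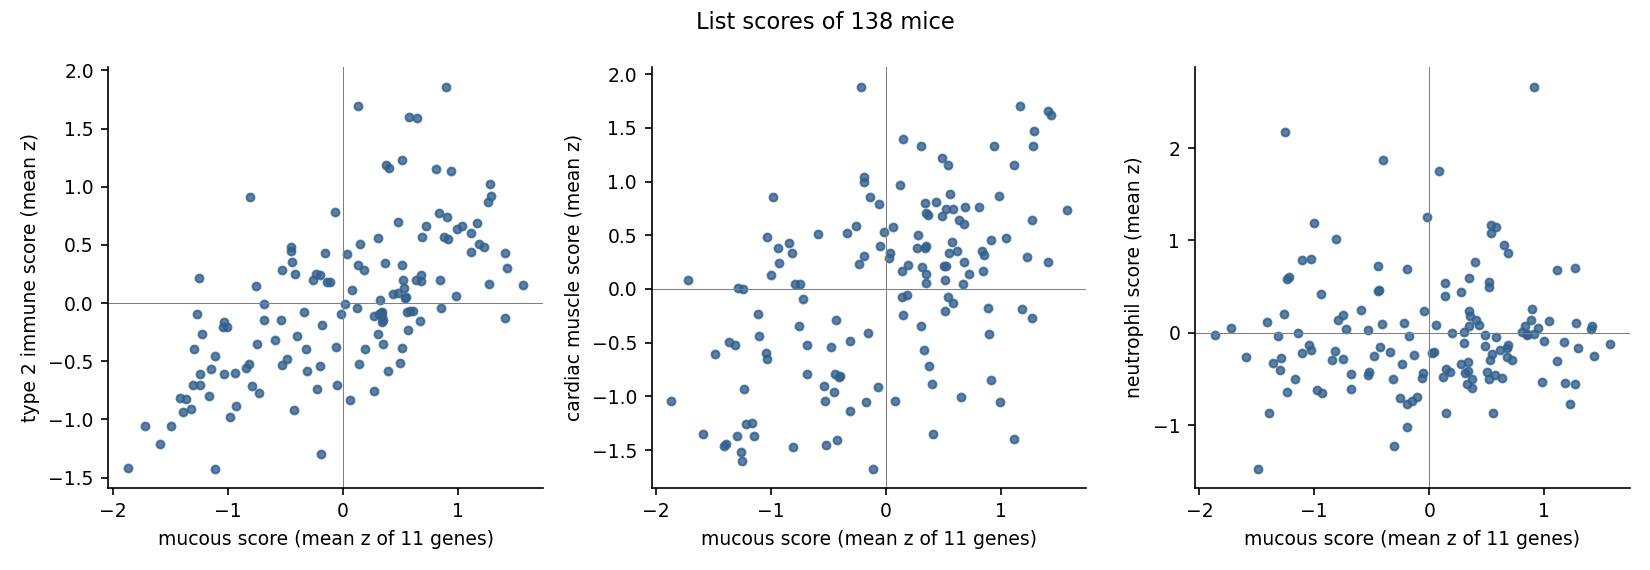
Each point is 1 of 138 mice, with the mucous score (mean z value of 11 genes) on the x axis and the type 2 immune, cardiac muscle or neutrophil score (mean z values) on the y axis. Pearson r with the mucous score was 0.634, 0.5 and 0.036 in this order.

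Of 16590 genes tested on both scores, 1107 rose with both and 1041 fell with both, where 229.1 and 222.1 would be shared if the calls were independent. None went in opposite directions (0 genes). The scores themselves correlated (r = 0.634), so the calls were not independent.

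The last score, of 10 neutrophil genes, asked which genes follow the content of neutrophils. The C-type lectin receptor Clec4d rose by 0.70 ± 0.06 (adjusted p = 1.29e-18), the receptor gene MRGPRA2 by 0.69 ± 0.05 (4.75e-21), the decoy receptor Il1r2 by 0.61 ± 0.05 (5.75e-19), the cytokine Il1b by 0.56 ± 0.05 (3.17e-15) and the protease inhibitor Cstdc4 by 0.71 ± 0.07 (1.46e-14). Asprv1 (0.59 ± 0.05), Slfn1 (0.44 ± 0.06), Trem3 (0.37 ± 0.04), Klra17 (0.36 ± 0.06) and Acod1 (0.35 ± 0.06), the enzyme that makes itaconate, rose as well. Prg2 rose by 0.43 ± 0.10 (0.00713) and the red cell anion exchanger Slc4a1 by 0.36 ± 0.10 (0.0186). Pon2, an enzyme of lipid peroxide breakdown (-0.25 ± 0.06, 0.00992), the signal protein Bmp3 (-0.34 ± 0.10, 0.0422) and Sh3tc2 (-0.17 ± 0.04, 0.00167) were among the genes that fell. All 12 named falling genes (these with Asgr1, Cyp4f15, Fmo5, Gpr182, St8sia2, Ppp1r13b, Diras2, Fzd2 and Dll4) lost their call under some alternative, as did Prg2 and Slc4a1.

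By limma 269 genes passed, 201 rising and 68 falling. Of the erythroid genes 2 of 8 rose (4 adjusted over the list alone), among them Slc4a1. Of the genes of neutrophilic inflammation 1 of 8 rose, Il1b (5 adjusted over the list alone), and of the interferon response 1 of 13, Rsad2 (0.34 ± 0.07; 10 adjusted over the list alone). Of the T cell markers 1 of 13, Ctla4, rose (3 adjusted over the list alone), and of the eosinophil markers 1 of 7, Prg2 (1 adjusted over the list alone). None of the 11 mucous and 16 type 2 immune genes passed on either adjustment. Among genes detected in every mouse, with the score rebuilt from the list genes left there, the count was 703, with 45.4% rising in place of 74.7%.

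**Figure D2:**
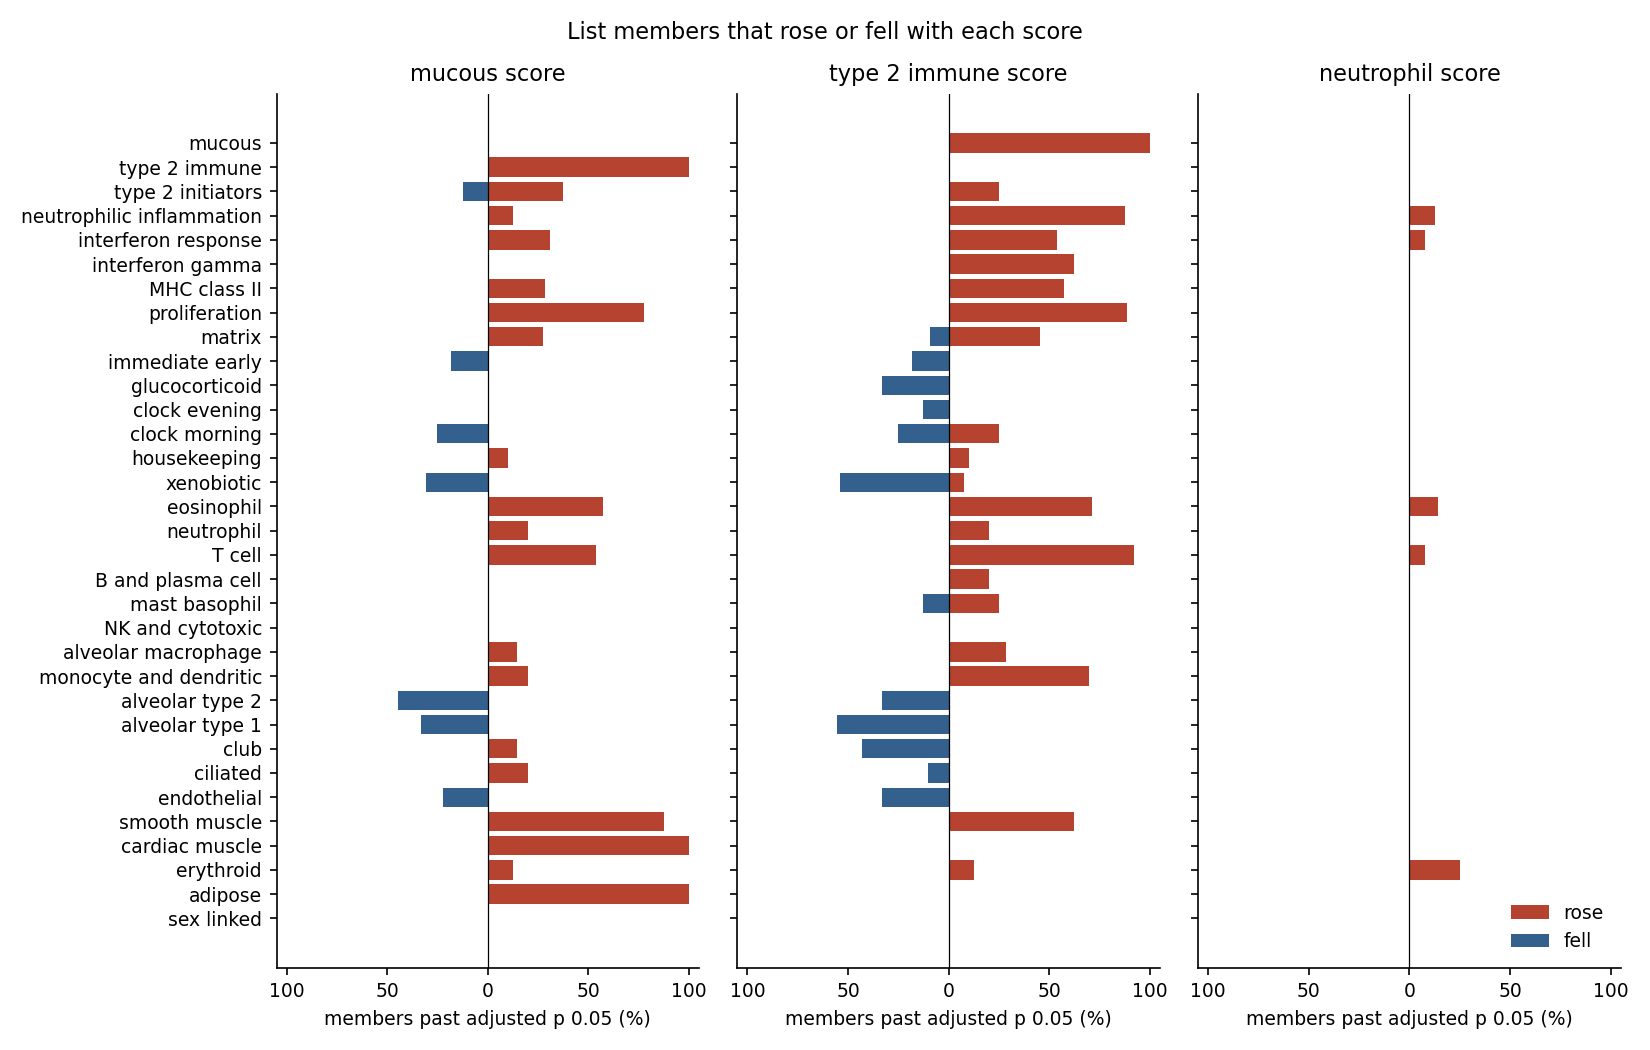
Bars give the percentage of each list's kept genes that passed adjusted p under 0.05 and rose (red, to the right) or fell (blue, to the left) with the mucous, type 2 immune and neutrophil scores. All 9 cardiac muscle genes rose with the mucous score and 0 of 9 passed with the type 2 immune score.

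Genes of most lists varied together from mouse to mouse. Their mean pairwise r passed in 29 of 33 lists, at the smallest p that 10000 random lists can give (0.0001, adjusted 0.000165) unless stated. The mean r was 0.656 for B and plasma cells, 0.649 for cardiac muscle, 0.638 for the mucous list, 0.632 for proliferation, 0.595 for adipose genes (adjusted p = 0.000861), 0.566 for the interferon response, 0.495 for ciliated cells, 0.451 for T cells, 0.418 for the interferon gamma response, 0.404 for NK and cytotoxic cells and 0.375 for the type 2 immune list. Clock genes of morning and evening phase reached 0.499 and 0.459, and immediate early genes 0.374. The mean r was 0.356 for matrix, 0.322 for neutrophils, 0.316 for erythroid genes, 0.303 for smooth muscle, 0.298 for monocytes and dendritic cells, 0.278 for neutrophilic inflammation, 0.239 for xenobiotic metabolism and 0.235 for glucocorticoid targets (adjusted p = 0.000314). Lower values that passed were 0.219 for endothelium (0.0006), 0.21 for eosinophils (0.00179), 0.177 and 0.176 for alveolar type 1 and type 2 cells (0.00457 and 0.00343), 0.136 for MHC class II (0.0279), 0.123 for alveolar macrophages (0.0245) and 0.11 for mast cells and basophils (0.0132). Housekeeping genes (0.026, adjusted p = 0.34), club cell genes (0.015, 0.419), initiators of type 2 immunity (0.013, 0.352) and sex-linked genes (-0.082, 0.889) did not pass. Mast cell genes lost the call among genes detected in every mouse (0.116, 0.233), and housekeeping genes gained it with the mean of a gene's probes (0.117).

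Scores of 35.6% of 528 pairs of lists correlated at adjusted p under 0.05 by permutation, 72 pairs negatively and the rest positively. For the pairs of this paragraph p was 1e-05 for r and rho alike, the smallest that 100000 permutations can give (adjusted over 528 pairs 8.52e-05 for r and 9.1e-05 for rho), unless stated. Clock genes of evening and morning phase were opposed (r = -0.798, rho = -0.827), and r was -0.808 without the 2 farthest mice and -0.751 and -0.827 within the low and the high range of the title number. Proliferation and matrix genes rose together (r = 0.756, rho = 0.753; 0.74 without 2 mice, 0.756 and 0.742 within ranges). Type 2 immune genes rose with eosinophil markers (r = 0.682, rho = 0.68; 0.65, 0.662 and 0.697) and with the mucous list (r = 0.634, rho = 0.657; 0.61, 0.653 and 0.612). They also rose with monocyte and dendritic cell markers (r = 0.571, rho = 0.503; 0.513, 0.465 and 0.658), T cell markers (r = 0.526, rho = 0.455; 0.473, 0.442 and 0.608) and genes of neutrophilic inflammation (r = 0.512, rho = 0.473; 0.465, 0.349 and 0.675). They were lower where xenobiotic genes were higher (r = -0.481, rho = -0.431; -0.403, -0.384 and -0.563). The mucous score rose with cardiac muscle (r = 0.5, rho = 0.479; 0.501, 0.429 and 0.551), and cardiac muscle with adipose genes (r = 0.538, rho = 0.544; 0.522, 0.466 and 0.612). The mucous and neutrophil scores did not correlate past the threshold (r = 0.036, p = 0.676, adjusted 0.802, rho = 0.057, p = 0.511). Of the pairs past the threshold, 187 kept their sign in both ranges, all but 1, and 63 passed in each range. The mucous and endothelial scores (r = -0.227, p = 0.00763, adjusted 0.0241, rho = -0.214, p = 0.0117) had r = 0.086 in the low range and -0.466 in the high range.

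**Figure D3:**
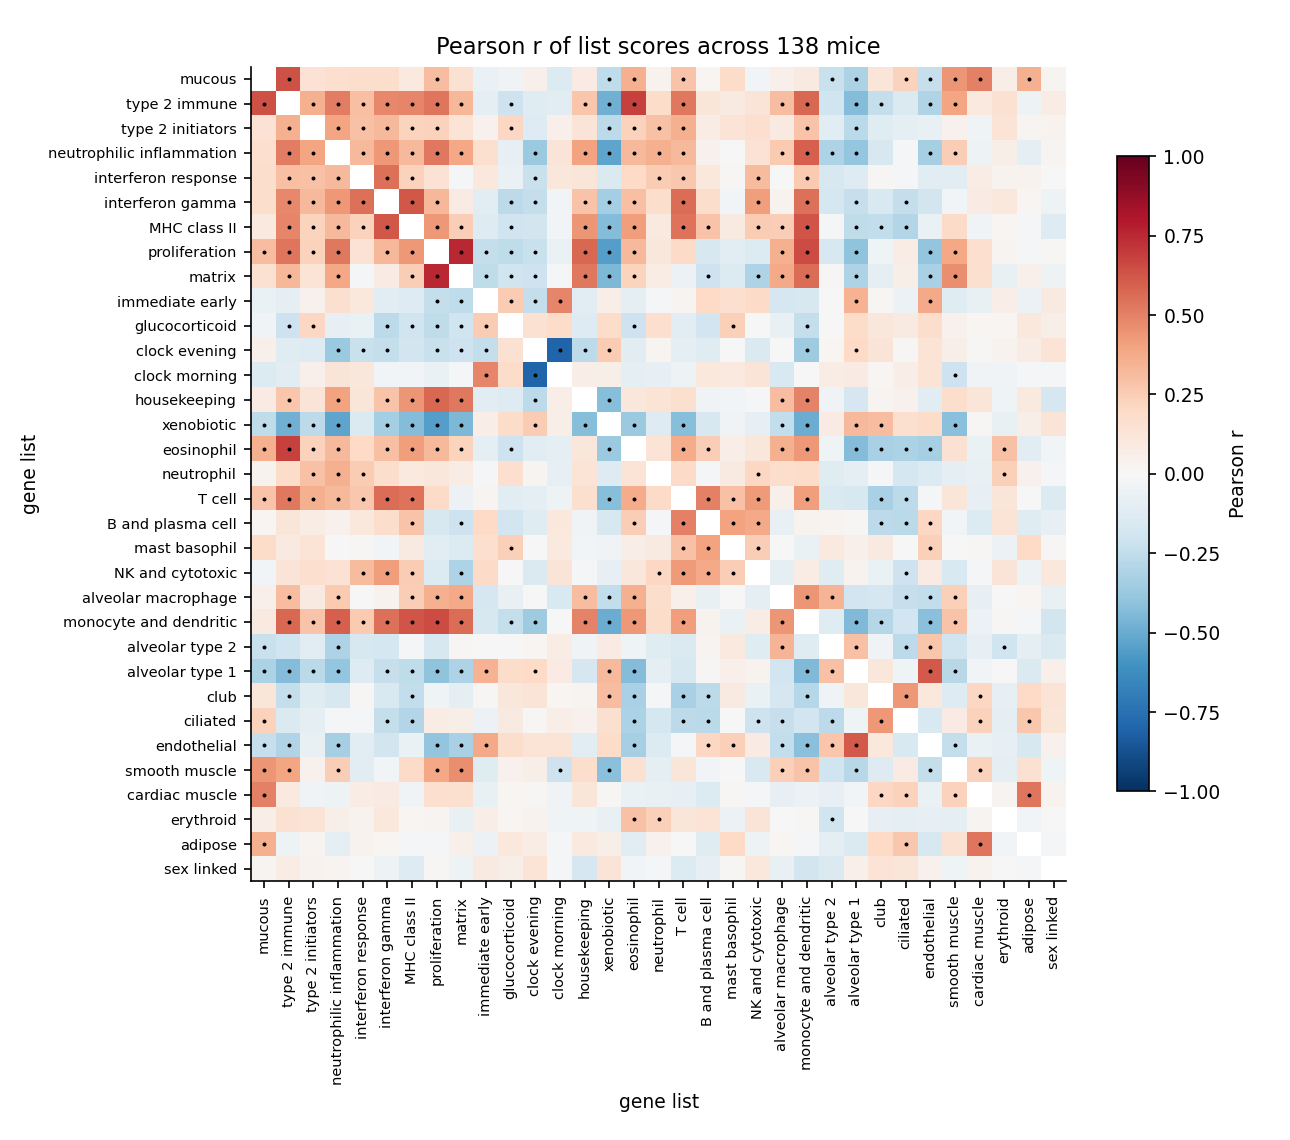
Pearson r between the scores of 33 gene lists over 138 mice, from blue (negative) to red (positive), with a dot where the adjusted permutation p was under 0.05. The type 2 immune score correlated at 0.682 with the eosinophil score and at -0.481 with the xenobiotic score.

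Of the 32 gene pairs fixed beforehand 25 could be tested and 20 passed, by permutation and adjusted over 25 pairs. Unless stated, p was 1e-05 for r and for rho, the smallest possible (adjusted 2.08e-05 for r). Clca1 followed Foxa3 (r = 0.792, rho = 0.865) and Spdef (r = 0.737, rho = 0.846), both transcription factors of goblet cells. Without the 2 farthest mice r was 0.783 and 0.74. Within the low and high range of the title number r was 0.768 and 0.805 for Foxa3, and 0.741 and 0.737 for Spdef. Clca1 followed Retnla (r = 0.568, rho = 0.518; 0.523 without 2 mice, 0.407 and 0.652 within ranges), and at r = 0.239 (p = 0.00473, adjusted 0.00657, rho = 0.27, p = 0.00141) Il13, the cytokine known to induce goblet cells, with 0.13 in the low range (adjusted p = 0.336) and 0.344 in the high range. The acute phase genes Saa3 and Lcn2 rose together (r = 0.652, rho = 0.655, 0.625 without 2 mice), as did Ifng and Cxcl9 (0.52, 0.387 and 0.407), Il13 and Il5 (0.518, 0.386 with p = 2e-05, and 0.438), and Il5 and Prg2 (0.463, 0.502 and 0.515). Il1rl1, the receptor of IL-33, correlated with Il13 at r = 0.246 (p = 0.00388, adjusted 0.00571, rho = 0.093, p = 0.279), but at 0.104 without 2 mice. Tbx21, a T helper cell transcription factor, correlated with Cxcl9 at r = 0.257 (p = 0.00229, adjusted 0.00362, rho = 0.18, p = 0.0361) and at 0.124 without 2 mice. The relation of Il1rl1 and Il13 rests on those mice, and that of Tbx21 and Cxcl9 does so for r. Ifng, Il13, Il5, Il1rl1 and Tbx21 lay near the floor (mean levels 4.64, 4.95, 4.80, 4.99 and 4.97). Correlations with these genes can therefore not be read as firm relations between transcript levels. Clca1 and Scgb1a1, which lay at the top of the scale, did not correlate past the threshold (r = -0.066, p = 0.446, adjusted 0.464, rho = -0.098, p = 0.253).

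Muc5ac, Il33, S100a8 and Sftpa1 each fell into 2 levels, and their pairs were tested within a level, 12 tests in all. The levels were found in these data, so these tests were not fixed beforehand. Over all 138 mice the pairs of Muc5ac passed by permutation for r and the others did not. Il33 and Clca1 had r = 0.16 (adjusted p = 0.0674, rho = 0.259, p = 0.00231), and Sftpa1 and Sftpc 0.166 (0.0605, rho = 0.396, p = 1e-05). S100a8 had r = -0.018 with Cxcl1 (adjusted p = 0.835) and 0.079 with Saa3 (0.391). Muc5ac followed Clca1 at r = 0.783 in the 50 mice of its lower level and 0.66 in the 88 of the upper (rho = 0.764 and 0.699), and Muc5b at 0.708 and 0.576 (rho = 0.684 and 0.581), each with p = 1e-05, the smallest possible. Il33, an alarmin of epithelium, correlated with Clca1 at r = 0.24 in 12 mice (p = 0.456) and 0.285 in the rest (permutation p = 0.00118, adjusted 0.00236, rho = 0.313, p = 0.00044). S100a8, a calcium-binding protein of neutrophils, correlated with Cxcl1 at -0.113 in 23 mice (p = 0.608) and -0.231 in the rest (p = 0.0131, adjusted 0.0225, rho = -0.215, p = 0.0218). Of the surfactant genes, Sftpa1 and Sftpc correlated at -0.374 in 30 mice (p = 0.0432, adjusted 0.0649, rho = -0.338, p = 0.0664) and 0.433 in the rest (p = 1e-05, rho = 0.486, p = 1e-05).

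The SD of a gene between mice had a median of 0.346 log2 (5th to 95th percentile 0.163 to 0.94), and 684 genes had an SD over 1. H2-Ea, a class II antigen gene, had the largest SD (3.14 log2, 95% bootstrap interval 2.96 to 3.27), and among genes with a symbol Fcer1g followed, a signalling chain of Fc receptors (2.98, 2.76 to 3.13). Csrp1 (2.96), Adgrf5 (2.74), Sspn (2.68), Emb (2.68), ITLNB (2.50), H2-Aa (2.45), S100a8 (2.42), Kng1 (2.40), Abhd16a (2.40), Nppa (2.36), Ang4 (2.35), Ear1 (2.34) and Adamts9 (2.29) came next. The 10 housekeeping genes had a median SD of 0.233, from 0.096 for Ppia to 0.517 for Gusb, which had 2 levels. Ppia, and Actb with an SD of 0.128, lay near the top of the scale (means 12.62 and 12.91), where a spread is hard to read. Of 684 genes with an SD over 1, 401 fell into 2 separated levels, and the share of genes with an SD over 1 was 4.12%, against 2.27% in the authors' deposited values.

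In all, 1178 of 16617 genes fell into 2 levels, of which 866 kept over 4 pooled SDs between means. In 1013 the low level was the rarer, and the smaller level held a median of 14% of mice (5 to 50). Senp2, a SUMO protease, had a mean of 4.63 in 21 mice and 9.91 in the rest (separation 17.9), and Isca1, an iron-sulfur assembly protein, 4.44 in 20 and 10.26 in the rest (17.7). The other genes with the widest separation were Sh3glb1 (low in 16 mice), Osr1 (8), Tapbpl (10), Dctn4 (23), Armc10 (23), LIP1 (23), Il18r1 (10), Wrn (9), Polr2g (12), Nifk (19), Pou6f1 (22), Maob (14) and Lonp2 (25). Among the fixed lists, H2-Ea was low in 42 mice (4.42 against 10.24, with further mice in between), H2-Aa in 59 (5.39 against 10.11), S100a8 in 23 (4.61 against 10.55) and Il33 in 12 (5.64 against 9.94). When probes had to be detected in every mouse, Isca1, Osr1, Dctn4 and Il18r1 were the only ones of the 15 widest that could be tested, by another probe, and all 4 lost the call, and 450 of 9670 genes then had 2 levels.

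**Figure D4:**
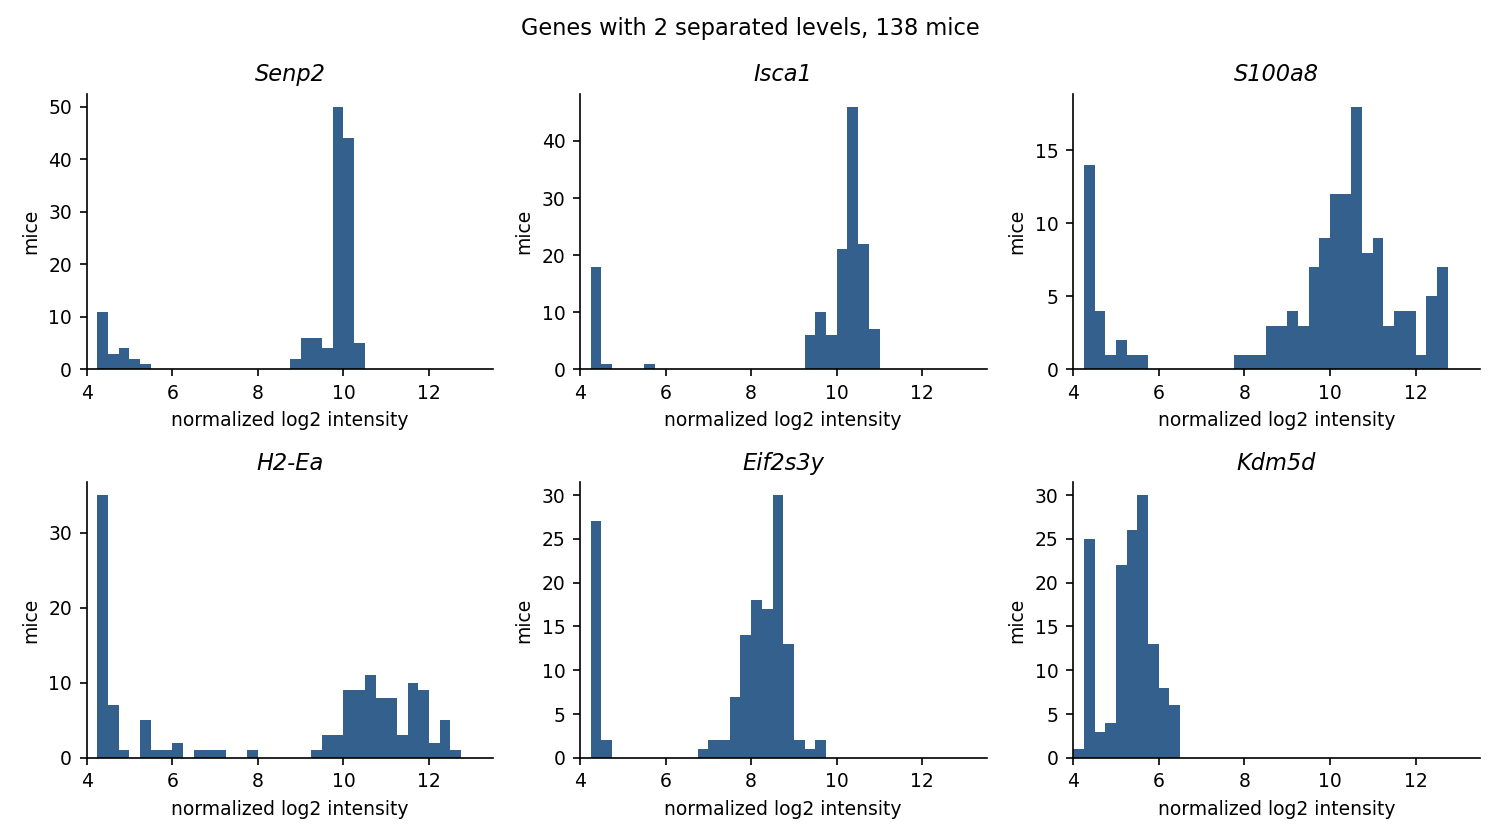
Histograms of normalized log2 intensity over 138 mice for Senp2, Isca1, S100a8, H2-Ea, Eif2s3y and Kdm5d, with the number of mice on the y axis. Senp2 has no mouse between 5.29 and 8.91, while H2-Ea has mice between its levels and the levels of Kdm5d adjoin without a wide gap.

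Different probes of a gene often gave different results. Over 5319 genes with more than 1 kept probe the median Pearson r across mice was 0.318, with 966 genes over 0.7 and 2549 under 0.3. In the tenth of genes with the largest SD the median was 0.451. Probes agreed closely for Clca1 (0.999), Timp1 (0.996), the clock repressor Nr1d1 (0.984), Arg1 (0.965), the T cell chain Cd3e (0.959) and the chitinase Chia1 (0.944). They did not for Cd8b1 (-0.009), Rtkn2 (-0.178), Ear10 (-0.208) and the kinase Jak1 (-0.265).

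The number that ends a mouse's title lay in 2 ranges, below 100 in 72 mice and above it in 64, and the labels used here do not say what it means. As a possible batch, it was tested by limma between ranges, and 0 of 16617 genes passed. At unadjusted p under 0.05 there were 656 genes, where 831 would be expected, and the lowest adjusted p was 0.987. Slopes on the mucous, type 2 immune and neutrophil scores differed between ranges for 0 genes each by limma (1022, 902 and 1623 at unadjusted p under 0.05, where 830 would be expected for each). For the neutrophil score the lowest adjusted p was 0.149. Position of an array in the deposited table, tested after the data had been seen, was related to 62.3% of all genes by limma. Whether that order is the order of processing is not known here. With position as a covariate 4132, 4684 and 255 genes passed on the mucous, type 2 immune and neutrophil scores.

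The mouse of line OR5308 was highest of all mice for each of 16 liver and skeletal muscle genes, lists written after its values were seen. Ahsg, a plasma protein made by liver, was 12.66 in it and 7.12 in the next mouse, Hpx, which binds heme in plasma, 13.01 against 7.04, and Acta1, the actin of skeletal muscle, 12.56 against 9.42. It had 345 genes over 1 log2 above every other mouse, where the most in any other mouse was 17. Markers of alveolar type 1 cells (median rank 1.5%, score -2.46), endothelium (6.6%, -1.86) and ciliated cells (9.1%, -1.13) were low in this mouse, those of club cells (23.4%, -0.42) and alveolar type 2 cells (21.9%, -0.59) less so, and those of smooth muscle (49.3%, 0.20), cardiac muscle (66.4%, 0.30) and adipose tissue (58.4%, 0.06) were not. Without it 3825, 4042 and 307 genes passed on the mucous, type 2 immune and neutrophil scores.

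**Figure D5:**
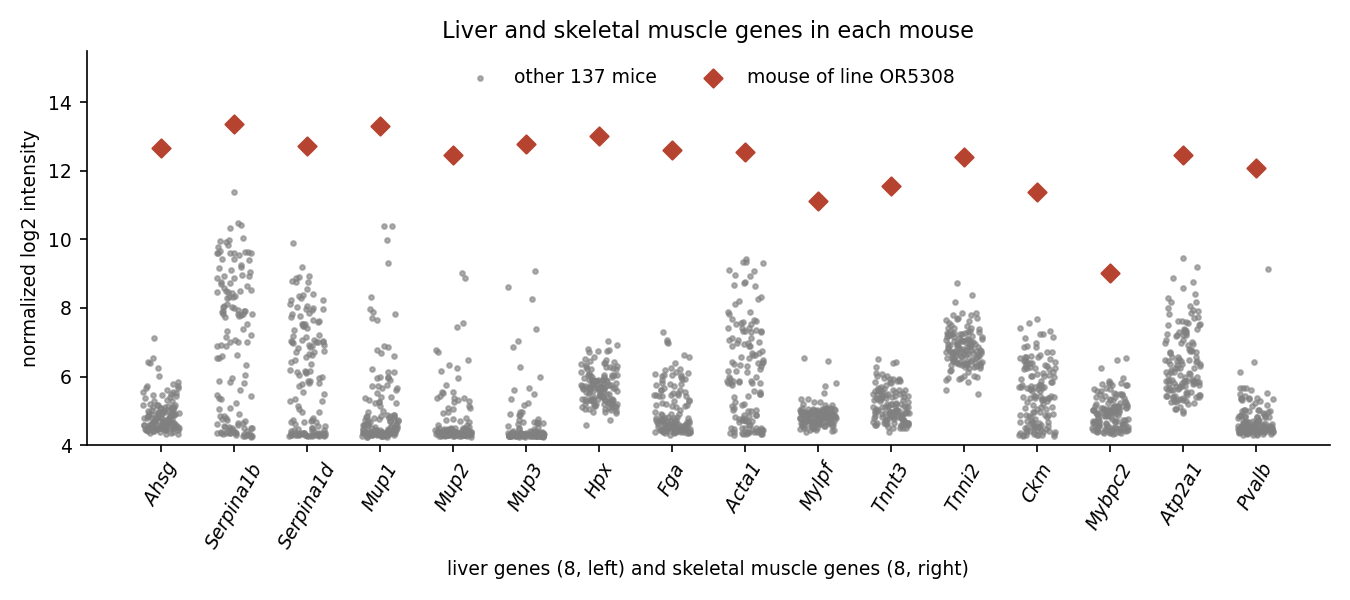
Normalized log2 intensity of 8 liver genes and 8 skeletal muscle genes, with grey points for the other mice and a red diamond for the mouse of line OR5308. The red diamond is the highest value for each of the 16 genes.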

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

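The alternatives chosen only after the data had been seen were position in the deposited table, the omission of the mouse of line OR5308 or of the 2 mice highest on the interferon gamma score, scores without 2-level genes, and the type 2 immune, mucous, cardiac muscle, airway and RNA-form scores as covariates. No paired analysis was possible because the labels give 1 group with 1 mouse per line. Over all alternatives, 996 of 1079 slopes of named genes kept direction and call, 80 lost the call and 3 reversed; with a score that holds the gene itself as a covariate (Arg1, Clca1, Muc5ac, Tff1, Nppa, Sln), the loss or reversal is built into the fit and shows nothing. For correlations of scores these were 262 of 301, 38 and 1, and 194 of 204 gene-pair values, 222 of 224 list values and 90 of 94 named 2-level values kept theirs. Of 100 counts and medians, 89 stayed within 1.5 times or the spread, and of 91 SDs of named genes 56 moved by less than their interval. The mucous count was 1784 with the type 2 immune score and 2329 with cardiac muscle, adipose, ciliated and smooth muscle scores as covariates (1784 to 4132 over all alternatives). Among genes detected in every mouse, fewer genes were tested and each score was rebuilt from the list genes left there. The type 2 immune count was then 2348 (to 4684 over all alternatives), 450 genes had 2 levels, 1.72% had an SD over 1, and 3 of 4 testable pairs passed, while the neutrophil count was 703 (194 to 703). The share of genes with an SD over 1 was 2.27% in the authors' deposited values, 2.25% without background correction and 2.32% without the filter, with more genes tested, against 4.12%. In the low range of the title number (72 mice) 76 pairs of lists passed, against 130 in the high range (64 mice), so the number of mice alone does not account for it. Signs reversed for Pon1 (0.004) on the mucous score with the type 2 immune covariate, for Muc5ac (-0.101) and Tff1 (-0.119) on the type 2 immune score with the mucous covariate, which holds both, and for the mucous and endothelial scores in the low range (0.086). No cause of these changes was tested, and the number of genes tested changed together with the genes of the scores. Slide blocks were not run because the files name no slides, thymus (2 kept genes) was left out of the tissue covariates, and the mucous count among genes detected in every mouse has no value, since fewer than 3 list genes stay. Signal over background limits genes near the floor.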

Other observations

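The tests of joint slopes, of Y-linked and mitochondrial levels, of drift along the deposited table, of other tissue, of nuclear and unspliced transcripts and of random reassignments were chosen only after the results were seen; those of probe variants, neighbouring genes and distortion of the array were written before.

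The mucous and type 2 immune scores were also fitted together, and the genes named here were chosen after their values were seen, with no test of a group. Capn9, of the gut epithelium, had a slope of 1.28 ± 0.07 on the mucous score and -0.10 on the type 2 immune score, Reg3g 1.36 ± 0.16 and -0.35, Scgb3a1 1.10 ± 0.18 and -0.42, and the secreted airway protein gene Bpifa1 1.11 ± 0.20 and -0.53. Foxj1 rose with the mucous score at 0.15 ± 0.03. Mmp12, the macrophage elastase, had 0.87 ± 0.10 on the type 2 immune score and -0.05 on the mucous score, Cxcl9 0.84 ± 0.12 and -0.26, Prg2 0.84 ± 0.12 and -0.12, Saa3 0.76 ± 0.14 and -0.18, and the amino acid oxidase Il4i1 0.76 ± 0.07 and -0.02. Retnlb (0.75 and 0.56) and SPRR2A (1.14 and 0.58) followed both. The scores correlate at 0.634, so slopes near 0 do not show that a gene follows only 1 of them.

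Of genes inherited from 1 parent, 2 of 4 on the Y chromosome and 6 of 16 mitochondrial probes fell into 2 levels. Eif2s3y was low in 29 mice and Kdm5d in 27, with 0 mice shared where 5.7 would be expected (Fisher's exact test, p = 0.00113), while Ddx3y was 9.74 to 11.8 in all 138 mice. The mitochondrial probes MTDNA_ND2 and MTDNA_ND4L were low in the same 18 mice, which were among the 23 low for MTDNA_COXII and the 34 low for MT-ND1. MT-CO2 was low in 28 mice and shared 1 with MT-ND1, where 6.9 would be expected (Fisher's exact test, p = 0.00264), and 0 with MTDNA_COXII, another name of the same gene, where 4.7 would be (p = 0.00418). These p-values were not adjusted for the 28 pairs of probes compared.

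Of 1178 genes with 2 levels, 394 had another kept probe, whose median r with the measuring probe was 0.344. This median lies between the bounds of 0.3 and 0.7 set for either answer. For these genes as a set, a sequence variant under the probe can therefore not be told apart from a level of the transcript. Single genes differed, and 130 had another probe at least as bright as the median gene. Of these, r was over 0.7 for 42, where that probe follows the level, and under 0.3 for 52, where it does not. The 2-level genes at most 5 kept genes apart split the mice more alike than others (median absolute r 0.367 over 382 pairs, against a median of 0.065 and a 95th percentile of 0.19 on different chromosomes), which is what an inherited difference at or near the gene predicts, but linked probe variants may give it too. Drift along the table is argued against as the whole cause: 74.4% of the genes kept the call after the trend was removed, against 71.5 to 74.7% after the same trend with the mice in 10 shuffled orders. Position in the table was related to 62.3% of all genes and to 13.2% of those with 2 levels (array median signal of neighbours correlated at 0.798), and a first test on the 13.2%, then a fixed bound on the share kept, left drift open and were replaced. Apart from the inherited difference, no biological explanation was tested.

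Cardiac muscle genes rose with the mucous score (r = 0.5) but not past the threshold with the type 2 immune score (r = 0.099, permutation p = 0.248, rho = 0.112, p = 0.193). Given the score of nuclear and unspliced transcripts, the partial r was 0.502 (95% interval 0.364 to 0.625). This argues against their share as the cause only as far as this score measures it. The score correlated at 0.054 with cardiac muscle and at 0.238 with the mucous score, so it could hardly change r. Whether its genes vary together was not tested. Given the ciliated, smooth muscle and adipose scores the partial r of the mucous and cardiac muscle scores was 0.345 (0.182 to 0.49), so more airway or hilar tissue in the piece, a hypothesis that could bring mucous and vein muscle cells together, cannot be told apart from another source: the interval spans the bounds set for either answer. The mucous and type 2 immune scores kept a partial r of 0.687 given the tissue scores. No biological explanation was tested.

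The mouse of line OR5308 stood apart from the others, also in its low scores of alveolar type 1 (-2.46), endothelial (-1.86) and ciliated (-1.13) markers, while smooth muscle (0.2), cardiac muscle (0.3) and adipose (0.06) scores were not low. The 16 genes first seen cannot test why, so 40 further liver and skeletal muscle genes were listed and read without the filter: it was highest of all mice for 90% of them, 19 of 20 liver and 17 of 20 muscle genes, such as Cps1 (11.76 against 4.65 in the next mouse) and Tnnc2 (12.88 against 8.25), which RNA of other tissue in this sample predicts. It was highest by over 1 log2 for 32, and for all 6 with a median over 6 in the other mice, such as Ass1 (8.89) and Eno3 (8.02), while the other 34 lay near the floor there and Serpinc1, Myh8, Chrna1 and Cav3 were not highest. Distortion of the whole array stays open: genes of testis, brain, pancreas and kidney had a median rank of 46.7% in it, but 7 of the 11 had a median under 6 in the other mice, near the floor, and the other 4 went both ways, with Mbp (7.65 against a median of 8.56) and Stmn2 (8.6 against 9.36) among the lowest and Slc12a3 (8.23 against 7.99) and Cela1 (9.61 against 6.11) among the highest values. A candidate source is liver and body wall or diaphragm muscle, and how it came there and any biological explanation were not tested.

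Random assignment of scores to mice argued against chance for the counts of the fits. As many genes as the real 3757, 4014 and 269 were found in 1 of 100 assignments each, the real one, which is the smallest share possible. The highest of the others were 1, 1 and 189 genes, so the margin was narrow for the neutrophil score. Each score is made from genes of the same arrays, so these counts show only that other genes vary with the list. For the title number, the real split had 0 genes by limma (656 at unadjusted p under 0.05). All 100 splits gave as many, which a real count of 0 fixes in advance, so chance cannot be excluded and nothing more follows. The highest other split called 225 genes (the median was 0). A structure of the samples is a possible reason, and it was not tested.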
